A study of Mus musculus with 6 samples.

How the data were processed

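RNA from 344SQ murine lung cancer cells was hybridised to Affymetrix mouse expression arrays with a biotin label, 1 array per sample, with extraction and labelling by the manufacturer's procedure per the labels' protocols. Per the labels, vectors expressing the hairpin RNAs were introduced by lipid transfection and cells were grown in RPMI medium with serum. The labels assign 3 samples to control shRNA and 3 to PIK3CA shRNA, and every sample was used.

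The deposited values are intensities on a linear scale, 1 per probe set and array, from 0.0359 to 17918.5 on each array. The 6 arrays shared this minimum and maximum and had nearly equal quartiles (lower quartile 37.5 to 37.6, upper quartile 533 to 535), so the authors' deposited intensities had been brought to a common distribution. The method is not given in the sources used here. Of the values on each array, 15% were below 16. The table holds no detection calls, and the number of arrays limits the precision.

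Intensities were scaled to a common median and taken to log2(intensity + 16). The pseudocount lowers the fold change of dim genes. The 64 Affymetrix control probe sets were left out of the tests. Probe sets were named through the platform annotation and a RefSeq gene table of assembly GRCm38.p6: 34945 had 1 gene symbol, 932 had several and 9160 had none listed. By gene identifier 34741 matched the RefSeq table, and 0 symbols changed. Each gene was represented by the probe set with 1 symbol whose mean log2 value over all 6 arrays was highest, which gave 18193 genes, 9010 of them with more than 1 probe set.

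Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no replicate block), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p 0.05. Adjusted p-values in the text come from this fit unless another test is named. Exact two-sided permutation tests over the 20 assignments of 3 against 3 arrays were used for single values, and their smallest p is 0.1. The 27 gene lists (788 distinct genes, 746 measured) were tested with camera at a preset correlation of 0.01, adjusted over the lists; the result of 1 list, which did not pass, is not reported here. None of the 6 calls held with an estimated correlation, where 0 lists passed, while fry, which tests whether a list's genes move on balance one way without comparing them with other genes, passed 16. The estimate was below the preset for the unfolded protein response (-0.011), G1/S (-0.025) and interferon (-0.009) lists. A higher correlation was therefore not what ended those calls. It was above the preset for the cholesterol (0.078), integrin (0.054) and ERK feedback (0.031) lists. Counts adjusted over the list alone use the limma p-values of the list's members.

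Genes were named by a rule: Pik3ca; the 15 largest rises and the 15 largest falls among genes past the threshold whose groups did not overlap and whose mean in the higher group was above the median of all genes; and up to 4 members per list with the smallest adjusted p. Genes known only by a clone identifier are counted, not named. Outside this rule, some gut-type genes, members of the gastrointestinal list, the ends of chromosome stretches and single list members were named after their values were seen, and control genes and the genes of the interferon and leukocyte tests are named as what was tested. The gene lists, the naming rule, the test and all alternatives but those said to be added were chosen before the data were examined. The values proved to be linear, for which the plan set the pseudocount and the scaling used here.

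Alternatives covered a replicate block, quantile normalization, median and upper-quartile centring, a filter on dim genes, the mean of probe sets or the probe set with the largest interquartile range per gene, all probe sets, array weights, an intensity trend with a robust prior, pseudocounts of 1 and 64, stricter thresholds, and leaving out each array. The removal of genes on 4 chromosomes and the removal of chromosome medians were added after the data were seen. Chromosome medians used genes above the median brightness, compared with 10000 shuffles of genes over the 20 chromosomes. Neighbours of a gene were the 5 tested genes on each side.

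The steps were tested on simulated data with 18193 genes. In these, 68, 66 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. Of them, 19.1%, 53.0% and 89.4% were recovered, with 6 false calls among 113. Far fewer genes were changed than the 2093 called in the data. The adjustment depends on that number, so the shares need not carry over. A list shifted by 0.3 was found with 0 other lists called, and a simulated shift of chromosome 8 by -0.25 was found at -0.25. Genes were drawn independently of each other, so the list check says nothing about correlation between members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.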

Results

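Gene expression was measured in 344SQ cells, a murine lung cancer line, carrying either a control short hairpin RNA (shRNA) or an shRNA against Pik3ca, which encodes the p110-alpha catalytic subunit of class I phosphoinositide 3-kinase (PI3K). Each group had 3 Affymetrix arrays, and 45101 probe sets were read per array as linear intensities. The median intensity per array lay between 134.1 and 134.7. The comparison asks which transcripts differ when Pik3ca is knocked down. Changes are PIK3CA shRNA minus control shRNA on the log2(intensity + 16) scale, which understates the change of dim genes. The number of arrays limits the precision. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

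Pik3ca, the targeted gene, was lower in the PIK3CA shRNA cells. Its brightest probe set fell from 2379 ± 66.3 (SD, n = 3) to 1236 ± 13.1 (SD, n = 3), which is 51.9% of the control intensity. In the limma fit over all genes the change was -0.94 with a standard error of 0.05 (adjusted p = 0.000762). Another 4 of the 6 Pik3ca probe sets also fell, to between 47.7% and 61.1% of control. The remaining, dim probe set read 139.9 ± 45.7 (SD, n = 3) in control and 135.1 ± 16.3 (SD, n = 3) in PIK3CA shRNA cells, with an exact two-sided permutation p of 1. For the 5 lower probe sets that p was 0.1, the smallest that 3 arrays against 3 allow.

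**Figure D1:**
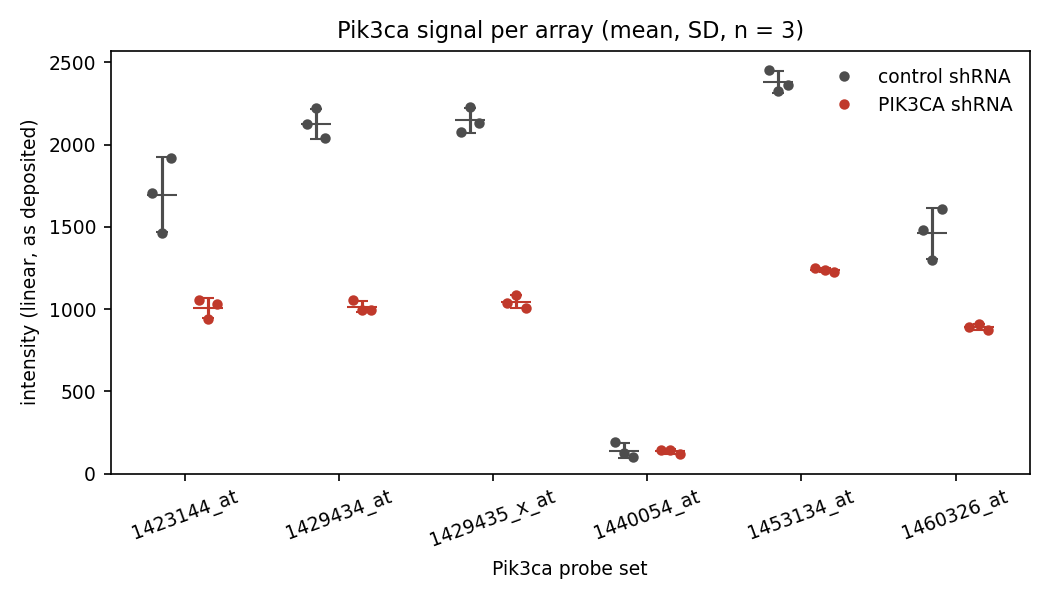
Intensity (linear, as deposited) of the 6 Pik3ca probe sets on each array, with points for arrays and lines for the mean and SD of 3 control shRNA (grey) and 3 PIK3CA shRNA (red) arrays. In all probe sets but the dim one with means of 139.9 and 135.1, the red points lie below all the grey ones.

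Among the 18193 genes tested, and of those above the median brightness in the higher group, Cdh10, a type II cadherin gene, had the largest rise in PIK3CA shRNA cells by its brightest probe set at the pseudocount of 16. It rose by 4.56 on the log2 scale, from an intensity of 48.8 ± 13.1 to 1494 ± 200 (SD, n = 3 each), but only 2 of its 4 probe sets rose and the mean over them rose by 1.64. Lgals4, a galectin made by gut epithelium, rose by 4.42 to the high intensity of 4173 ± 139 (SD, n = 3). At a pseudocount of 64 Lgals4 rose more than Cdh10 (4.12 against 3.79), and at a pseudocount of 1 Slc43a3 did (5.43 against 4.94). Nid1, which encodes the basement membrane linker nidogen-1, rose from 113 ± 4.42 to 1948 ± 42.7 (SD, n = 3 each), and Cxcl5, a neutrophil-attracting chemokine, rose from 15.8 ± 1.96 to 483 ± 68.9 (SD, n = 3 each). The largest fall at the pseudocount of 16 was in Arfgef3, from 350 ± 91.3 to 13.4 ± 8.47 (SD, n = 3 each), and S100a4, a calcium-binding protein often used as a mesenchymal marker, fell from 3228 ± 98.5 to 483 ± 68.4 (SD, n = 3 each). At a pseudocount of 64 S100a4 fell more than Arfgef3 (-2.60 against -2.40).

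The limma test with Benjamini-Hochberg adjustment placed 2093 genes (11.5%) past adjusted p 0.05, 1070 of them higher and 1023 lower in PIK3CA shRNA cells. Of these, 238 were higher and 104 lower by at least 2-fold, and 69 were higher and 10 lower by at least 4-fold. The 3 arrays of each group did not overlap in any of the 2093 genes. Over all genes, groups did not overlap in 6015 (33.1%), against 10% by chance. Pearson's r across the non-control probe sets was 0.982 to 0.984 between arrays of the same group. It was 0.974 to 0.977 between arrays of different groups, and probe sets are not independent replicates. Of the called genes, 1250 had more than 1 probe set, and in 279 of them another probe set passed in the same direction, while in 4 another probe set passed in the opposite direction. Leaving out 1 array lowered the count to 1047, 987 and 1069 without control replicates 1, 2 and 3, and to 963, 1138 and 945 without PIK3CA shRNA replicates 1, 2 and 3. It was 3192 with an intensity trend and robust prior, 636 at adjusted p 0.01, and 1164 when genes on chromosomes 2, 5, 6 and 8 were left out, a choice made after the data were seen.

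Of the other genes with the largest rises, Cdh17, the liver-intestine cadherin, rose from 323 ± 33.4 to 3444 ± 85.7 (SD, n = 3 each). Muc1, a transmembrane mucin, rose by 3.21, and Thbd, which encodes the anticoagulant receptor thrombomodulin, rose by 3.14. Slc43a3, a nucleobase transporter, rose by 3.68 from an intensity of 5.12, which is below the pseudocount. Rises were also seen in Sim2, a basic helix-loop-helix transcription factor (3.69), Calml4, a calmodulin-like protein (3.66), the haem-binding protein gene Hebp1 (3.65), the monoamine oxidase gene Maob (3.59) and the sialic acid acetyltransferase gene Casd1 (3.48). Arap3, whose product is a GTPase-activating protein that binds the PI3K lipid product, rose by 3.34 with a standard error of 0.12 (limma adjusted p = 0.000179). The remaining 1 of the 15 largest rises was in a transcript with only a clone identifier. The adjusted p of the 15 ran from 3.89e-05 for Nid1 to 0.00296 for Muc1.

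Among the other large falls, Prkd1, which encodes protein kinase D1, fell by 2.77 on the log2 scale, and Rps6ka6, a ribosomal S6 kinase of the ERK pathway, fell by 2.19. Sigirr, an inhibitor of interleukin-1 and Toll-like receptor signalling, fell from 1362 ± 113 to 240 ± 38.6 (SD, n = 3 each). Aqp5, the water channel of alveolar type I cells and glands, fell from 400 ± 9.48 to 68.0 ± 7.20 (SD, n = 3 each). Falls of between 1.82 and 2.73 on the log2 scale were also found in Tchh (-2.73), Cd300lb (-2.35), the forkhead factor gene Foxd1 (-2.01), the protocadherin gene Pcdh19 (-1.91), Hmgn3 (-1.91), Sfmbt2 (-1.88), the translational regulator gene Cpeb1 (-1.84) and Mei4 (-1.82). The remaining 1 of the 15 has only a clone identifier. The adjusted p of the 15 ran from 0.000163 for Prkd1 to 0.00285.

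**Figure D2:**
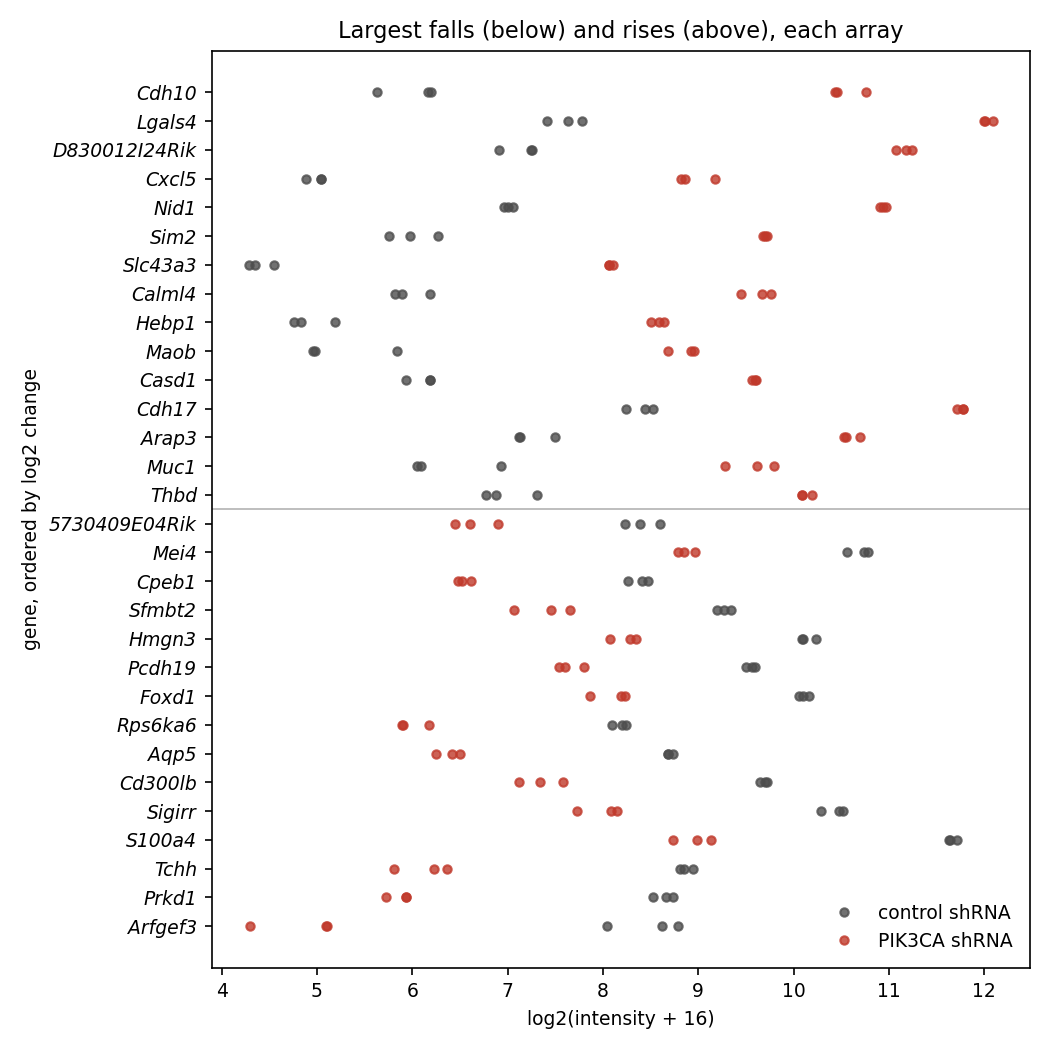
Log2(intensity + 16) of the 15 genes with the largest rise (above the line) and the 15 with the largest fall (below it), 1 point per array, for control shRNA (grey) and PIK3CA shRNA (red). The 3 red points of each gene lie to one side of its 3 grey points, from Cdh10 (4.56) at the top to Arfgef3 (-3.65) at the bottom.

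Of 27 gene lists fixed in advance, 6 passed camera with its preset correlation, and the lists of the unfolded protein response and of G1/S genes were the 2 that were lower. In the unfolded protein response list, 9 of 22 measured genes fell and 0 rose (1 higher and 14 lower adjusted over the list alone). Among them were Dnajc3 (-0.79) and Creld2 (-0.73), which act in folding in the endoplasmic reticulum, the translocon subunit gene Sec61b (-0.64) and Manf (-0.52). The list's camera adjusted p was 6.80e-06, and adjusted p = 0.129 with an estimated correlation. Of 38 measured G1/S and DNA replication genes, 8 fell and 0 rose (0 higher and 9 lower adjusted over the list alone). They included the cyclin gene Ccne2 (-0.64), the origin-licensing gene Cdc6 (-0.55), and the replicative helicase genes Mcm5 (-0.50) and Mcm10 (-0.44). The camera adjusted p was 0.0112, and adjusted p = 0.204 with an estimated correlation. It was 0.0639 with the probe set of largest interquartile range.

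Among the lists that were higher, cholesterol synthesis had 4 of 21 measured genes higher and 0 lower (9 higher and 0 lower adjusted over the list alone). Fdps rose by 0.59, Idi1 by 0.58 and Fdft1 by 0.55, all enzymes of the mevalonate and squalene route, and the sterol transporter gene Stard4 rose by 0.49. Another Fdft1 probe set, the one with the largest interquartile range, read -0.24 and was not past the threshold. The list's camera adjusted p was 0.00470, and adjusted p = 0.291 with an estimated correlation. Among integrin, laminin and adhesion genes, 8 of 34 rose and 2 fell (10 higher and 2 lower adjusted over the list alone). Beside Nid1, the collagen-binding integrin genes Itga1 (2.70) and Itga2 (1.17) and the adhesion molecule gene Alcam (0.65) rose, while Icam1 (-0.45) and the vinculin gene Vcl (-0.42) fell, the latter named after its value was seen. Itga1 went from an intensity of 22.1 to 222, below the median brightness of all genes in both groups. The camera adjusted p was 0.00857, and adjusted p = 0.291 with an estimated correlation; it was 0.0528 without control replicate 1.

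Interferon response genes were also higher as a list, with 8 of 36 measured members higher and 1 lower (11 higher and 1 lower adjusted over the list alone). The RNA sensor gene Ifih1 rose by 1.12, Xaf1 by 1.51, and the interferon-inducible GTPase genes Gbp2 and Igtp by 1.01 and 0.70. Gbp2 went from an intensity of 67.4 to 152, below the median brightness of all genes in both groups. The lower member was Oas3 (-0.74), named after its value was seen. The camera adjusted p was 0.0112, and adjusted p = 0.204 with an estimated correlation. With dim genes left out it was 0.0558. Leukocyte markers had 2 of 17 measured members higher and 0 lower (2 higher and 0 lower adjusted over the list alone), the Fc receptor gene Fcgr3 (1.47) and Cd14 (0.65), with a camera adjusted p of 0.454.

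Genes of ERK pathway feedback and immediate early response had 7 of 27 members higher and 3 lower (12 higher and 3 lower adjusted over the list alone). Spry2 (0.68) and Spred1 (0.48), inhibitors of receptor signalling to ERK, rose with Hmga2 (0.51). Egr3, an early growth response transcription factor gene, moved the other way at -0.96, and another Egr3 probe set read 0.72 without passing the threshold. The other falls were in Egr2 (-0.55) and Dusp4 (-0.29), named after their values were seen. The list's camera adjusted p was 0.0303, and adjusted p = 0.291 with an estimated correlation. It was 0.0679 without control replicate 1, 0.0507 without control replicate 2, 0.0770 without PIK3CA shRNA replicate 1, 0.0838 with dim genes left out, and 0.0716 on ranks.

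Components of the PI3K and AKT pathway showed changes in both directions: 3 of 33 rose and 4 fell (3 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.253). Besides Pik3ca itself, the forkhead factor gene Foxo3 (-0.57) and the AKT phosphatase gene Phlpp1 (-0.44) fell, and Tsc1, an inhibitor of mTOR complex 1 signalling, rose (0.64). Of 30 FOXO target genes, 5 rose and 3 fell (7 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.742). The ubiquitin ligase gene Fbxo32 (0.83), the pro-apoptotic gene Bcl2l11 (0.50) and Gadd45a (0.48) rose, and the transcriptional repressor gene Bcl6 fell (-0.71). Among EGF-family ligands, ERBB receptors and GATA factors, 4 of 20 rose and 4 fell (4 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.843). The neuregulin genes Nrg1 (-1.39) and Nrg2 (-0.73) fell with Gata3 (-1.93), and the GATA cofactor gene Zfpm1 rose (1.05). Gata3 was dim in both groups, at an intensity of 97.6 in control and 14.4 in PIK3CA shRNA cells.

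The remaining metabolic and growth lists did not pass as lists. Of 17 fatty acid synthesis genes, 1 rose and 2 fell (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.880), with the desaturase gene Scd1 at -0.84. Of 29 glycolysis and hypoxia genes, 5 rose and 3 fell (7 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.756). Carbonic anhydrase Car9 rose (0.60) but stayed below the median brightness of all genes. Ankrd37 (-1.04), the prolyl hydroxylase gene Egln1 (-0.78) and the lactate transporter gene Slc16a3 (-0.73) fell. Amino acid and ATF4 response genes had 2 of 31 higher and 6 lower (2 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.126), including the leucine transporter gene Slc7a5 (-1.01) and Nupr1 (-0.57) among the falls and Cebpb (0.44) among the rises. MYC target and ribosome biogenesis genes had 2 of 31 higher and 3 lower (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.756), and the helicase gene Ddx21 was at -0.38. For G2/M genes, 2 of 39 rose and 5 fell (4 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0981), with Hmmr (-0.78) and the survivin gene Birc5 (-0.54) lower and Ube2c (0.51) higher. That list passed with the mean of all probe sets per gene (adjusted p = 0.0112), with the probe set of largest interquartile range (0.0242), and with chromosome medians taken out of each array (0.0119), the last chosen after the data were seen. Of 28 p53 target genes, 1 rose and 2 fell (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.742), namely Trp53inp1 (0.56), Sesn1 (-0.39) and the CDK inhibitor gene Cdkn1a (-0.43). Autophagy and lysosome genes had 3 of 33 higher and 6 lower (4 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.756), with the hexosaminidase gene Hexa (-0.88) and the proton pump gene Atp6v0d1 (-0.77) lower.

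Markers of cell state were mixed. Of 37 epithelial markers, 2 rose and 1 fell (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.258). The tight junction gene Ocln (0.99) and the protease inhibitor gene Spint1 (1.10) rose, and Mal2 fell (-0.91). Of 37 mesenchymal markers, 3 rose and 7 fell (4 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.403). Besides S100a4, the matrix gene Thbs1 (-0.91) and the transcription factor gene Snai2 (-0.49) fell, and N-cadherin, encoded by Cdh2, rose (0.51). As the mean of their probe sets, Snai2 read -0.08 and Cdh2 0.32, neither past the threshold. Lung lineage markers had 3 of 27 higher and 1 lower (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.742), with the nuclear receptor gene Hnf4a (1.14), Muc1 and the forkhead gene Foxa1 (0.38) higher and Aqp5 lower. Being on this list does not make a gene particular to lung, which holds for Hnf4a and Muc1 among the rises. Fibroblast markers had 0 of 16 higher and 1 lower, Dcn at -0.75 (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.206). Endothelial markers had 0 of 12 higher and 0 lower by limma (0 and 0 adjusted over the list alone; camera adjusted p = 0.843).

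Genes of invasion, cytokine and developmental signalling included some large single changes. Of 35 metalloproteinases and other extracellular proteases with their inhibitors, 6 rose and 3 fell (7 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0981, and 0.0412 without PIK3CA shRNA replicate 1). The collagenase gene Mmp13 (1.69), Mmp10 (1.01), the plasminogen activator gene Plat (1.23) and the metalloproteinase inhibitor gene Timp3 (2.07) rose. Of 31 NF-kB and cytokine genes, 5 rose and 1 fell (7 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0981, and 0.0483 without PIK3CA shRNA replicate 2), with Cxcl1 (0.49) and Tnfaip2 (0.72) higher beside Cxcl5. TGF-beta response genes had 3 of 27 higher and 4 lower (4 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.756), with the ligand gene Tgfb3 (1.62) and Id2 (0.78) higher and Ccn1 (-0.68) lower. Tgfb3 was dim, going from an intensity of 10.6, below the pseudocount, to 66.2. Notch and Wnt genes had 3 of 31 higher and 3 lower (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.843), with the Notch ligand gene Jag1 (1.14) higher and the Wnt receptor gene Fzd2 (-0.76) lower. With the mean of each gene's probe sets, Fdps, Fdft1, Mcm10, Nrg2, Egr3, Spred1, Plat, Tnfaip2, Sesn1 and Cdkn1a also lost their calls, as did Fbxo32, Bcl2l11, Fdft1, Mcm5, Ddx21, Egr3, Trp53inp1 and Sesn1 with the probe set of largest interquartile range. The median, mean and camera direction differed in sign for the FOXO, glycolysis and hypoxia, autophagy and lysosome, and lung lineage lists.

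**Figure D3:**
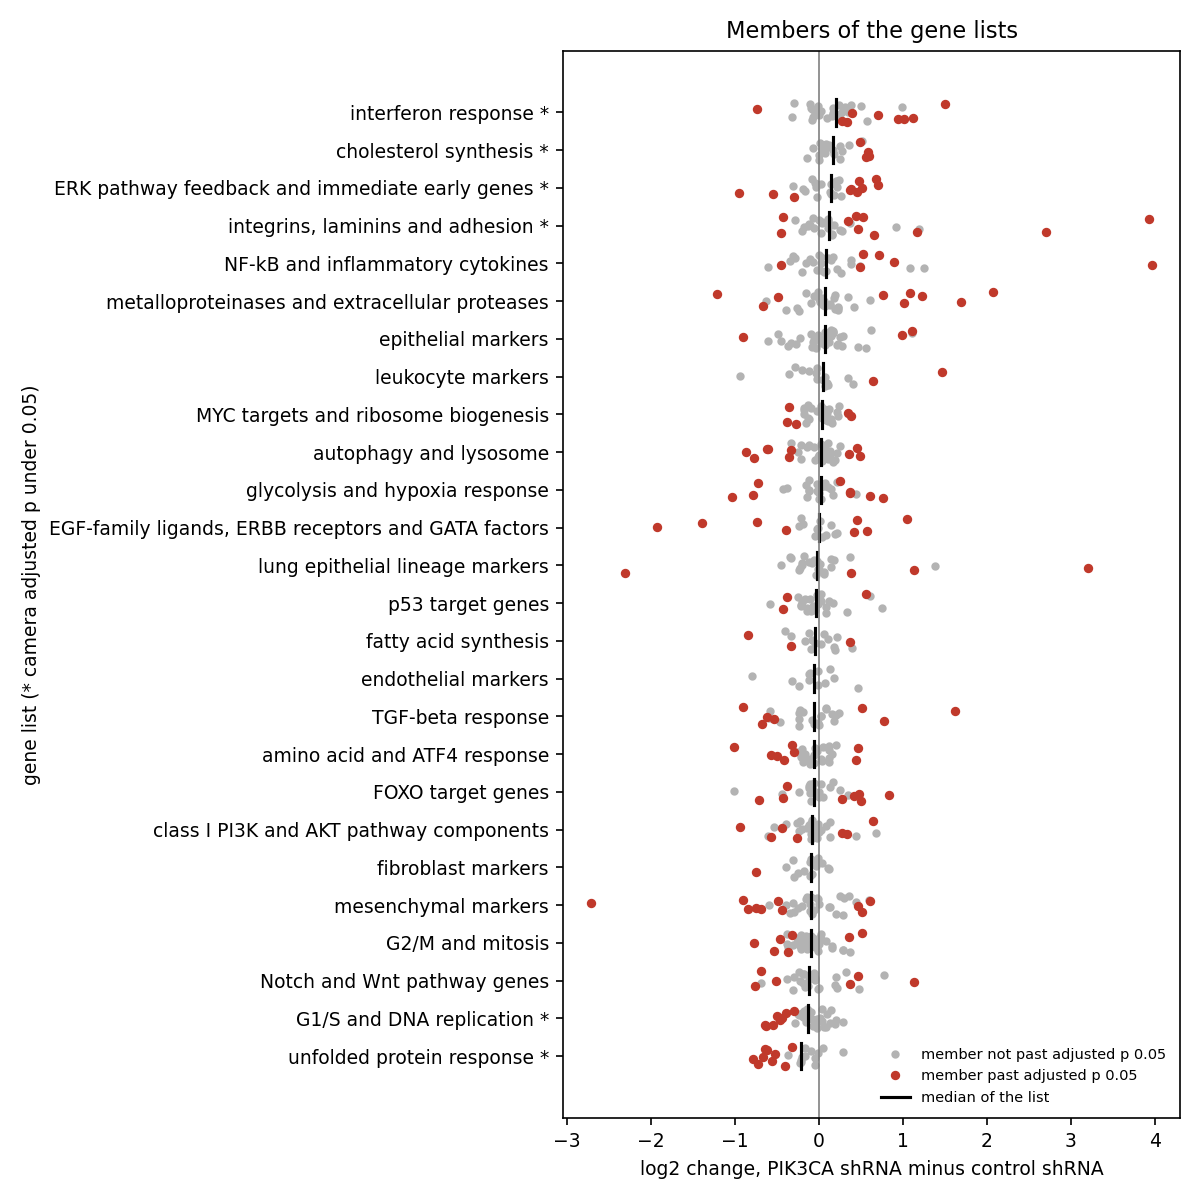
Log2 change (PIK3CA shRNA minus control shRNA) of each measured member of the gene lists reported, with red for members past adjusted p 0.05, grey for the others and a bar at the list's median. Lists with an asterisk passed camera with its preset correlation, 4 of them higher and 2 lower.

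Changes were not spread evenly over the chromosomes (GRCm38.p6), an examination made after the data were seen. Among the 9077 brighter genes that could be placed, the median change was 0.20 on chromosome 2 and 0.18 on chromosome 6, against -0.15 on chromosome 5 and -0.25 on chromosome 8. Each had a permutation p of 0.0001, the smallest that 10000 shuffles of genes over chromosomes can give, and genes are not independent replicates. On chromosome 8, 26 genes rose and 198 fell, and 86.3% of its brighter genes were lower. Of the 20 chromosomes, 7 passed an adjusted p of 0.05; the other 3 had smaller shifts, with medians of 0.04 on chromosome 12 (adjusted permutation p = 0.00760), 0.02 on chromosome 7 and -0.05 on chromosome 19 (adjusted permutation p = 0.00857 for both). Chromosomes 2, 5, 6 and 8 held 6 of the 30 genes with the largest changes, namely Cxcl5, Slc43a3, Hebp1, Casd1, Thbd and Sfmbt2, and 781 of the called genes. With the chromosome medians taken out of each array, 1567 genes passed, 1428 of which were among the 2093. Of the 131 genes named by the rule besides Pik3ca, 92 remained when genes on these chromosomes were left out. In the fit with chromosome medians taken out, 11 of the 131 lost their call. The changes given above for list members on these chromosomes include the chromosome-wide shift.

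**Figure D4:**
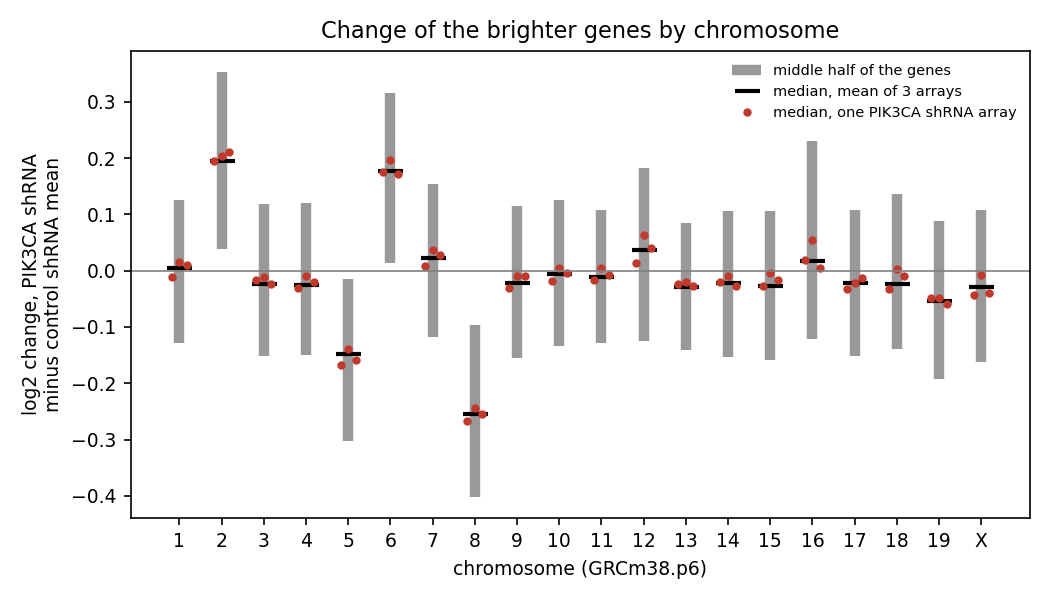
Log2 change of the brighter genes by chromosome (GRCm38.p6), with grey bars for the middle 50% of genes, black lines for the median of the mean change and red points for each PIK3CA shRNA array against the control mean. All 3 arrays lie near 0.20 on chromosome 2 and near -0.25 on chromosome 8.

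As a sign of RNA quality, the difference between the 3' and 5' control probe sets of Gapdh was -0.38 ± 0.04 in control and -0.36 ± 0.01 in PIK3CA shRNA cells (log2, SD, n = 3 each; exact two-sided permutation p = 0.6), and that of beta-actin was 0.15 ± 0.05 against 0.18 ± 0.01 (SD, n = 3 each; exact permutation p = 0.5). Between the 3' and middle probe sets, the groups differed by 0.01 for Gapdh (exact permutation p = 0.9) and by 0.04 for beta-actin (exact permutation p = 0.3), the latter slightly above the SD within either group. The 18S ribosomal RNA 5' control probe set read 557, 4964 and 6695 on the 3 control arrays and 1257, 953 and 1275 on the 3 PIK3CA shRNA arrays.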

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

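The tests of RNA degradation, of the chromosome shifts, of dim signal, of single arrays, of the 10 splits, of the share of called genes with moving neighbours and of the interferon genes were chosen or completed only after the result was seen; the other tests reported here were set before their values were seen. Among the 10092 probe sets with no gene symbol or several, which the comparison by gene does not use, 131 were higher and 107 lower in PIK3CA shRNA cells by limma at adjusted p 0.05. At the pseudocount of 16 the largest rise was 5.47, in a probe set listed for 2 genes that went from an intensity of 7.06 to 1021, and the largest fall was -3.48, in a probe set with no listed gene that went from 432 to 24.1.

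With Pik3ca at 51.9% of control, 2093 genes were called, and the 10 splits of the 6 arrays are too few for a share under 0.05: the labelled split was the 1 split with as many genes, and the highest other split called 1. RNA degradation is argued against by a largest group difference of 0.0302 in 3' minus 5' signal, far below the median called change of 0.51. On chromosomes 2, 5, 6 and 8, picked for their shifted medians, 84.3% of the called genes went with the median, a share that this choice largely fixed; copy-number differences between the cell populations compared may lie behind the shifts, which had the same sign in all 4 successive stretches of each chromosome, but no value here decides it. Shifts of whole chromosomes as the whole cause are argued against, because 1567 genes were still called with chromosome medians taken out. Shifts of shorter stretches, such as that on chromosome 16 with a median of 0.50, are not removed this way. For 15.8% of called genes the neighbours moved with them by at least 0.2, against at most 2.87% in 100 permutations. Called genes thus moved with their neighbours more often than when genes were shuffled. How much of the changes copy number could explain is not settled by this share, since the step of 0.2 exceeds the shifts of chromosomes 2, 5 and 6. A clonal difference between the cultures, an effect of lower Pik3ca and any other effect of the hairpin vectors all stay open. No DNA measurement was used here.

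Genes known from gut epithelium stood out among the large rises, an impression formed from the data: Lgals4, Calml4, Cdh17, Muc1 (also in the lung lineage list), Apob, Cdx2, Tff2 and Avil rose by 2.75 to 4.42, and the last 4 of these lie outside the 15 largest rises. The 8 genes were picked for large rises, which largely fixed the tests of dim signal and of a rise carried by 1 array. Their values are given as description. The lowest intensity on any PIK3CA shRNA array was 606 for the genes other than Tff2, over the median of 246 for all genes. Without a pseudocount, the lowest PIK3CA shRNA array exceeded the highest control array by at least 2.52 on the log2 scale in each of the 8. Dim signal is least settled for Tff2, with a lowest value of 201.7. Of the 8 genes, 0 lay among neighbours with a median change of at least 0.2, a step that cannot register smaller shifts. The neighbours' medians ran from -0.18 for Cdx2 to 0.15 for Muc1, far below the rises of the genes themselves. This argues against a copy-number change of the size of these rises that is shared with neighbouring genes. Smaller shared shifts are not excluded. A list of other gastrointestinal epithelial genes, written before its values were seen, was higher by camera (p = 0.000819, and p = 0.0305 with an estimated correlation), with 11 of 50 measured members higher and 1 lower. The median change over the 50 measured members was 0.08, and several of the higher members were dim. A wider shift toward gut-type expression in the PIK3CA shRNA cells is therefore only a hypothesis, which was not tested further. An effect of Pik3ca, a clonal difference and any other effect of the hairpin vectors were not separated.

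Interferon response genes were higher as a list by camera (adjusted p = 0.0112), a call that was lost with dim genes left out (0.0558) and at adjusted p = 0.204 with an estimated correlation, with values from 0.00153 to 0.204 over its alternatives. A response to double-stranded RNA made by the vectors could take part and stays open: 10 direct targets of that response had a median change of 0.0740 and 0 of 10 were called by limma, with 1, Rsad2, at an unadjusted p under 0.05, but they include dim genes such as Oasl2, Mx1 and Mx2 and none of the list's called members. Leukocytes in the cultures stay open as well. The 5 pan-leukocyte genes Ptprc, Tyrobp, Laptm5, Coro1a and Cd52 had a median change of -0.200 and none was called, but their intensities were 8.46 to 320 in PIK3CA shRNA cells, 1 of the other Laptm5 probe sets was higher, and they leave out Fcgr3 (1.47) and Cd14 (0.65), which were called higher. An interferon-type response in the cells themselves, to which the called members Ifih1, Xaf1, Gbp2 and Igtp could belong, was not separated from these, and its link to Pik3ca was not tested.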

How the results depend on the processing

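Leaving out genes on chromosomes 2, 5, 6 and 8 and taking out chromosome medians were the alternatives chosen after the result was seen. Pik3ca stayed past the threshold and lower under all 19 alternatives, from -1.06 to -0.74 (adjusted p 1.34e-05 to 0.0264). The count of 2093 called genes (1070 higher, 1023 lower) moved by over 1.5 times in these settings. It was 3192 (1606 and 1586) with a trend and robust prior, 342 (238 and 104) with a 2-fold change required, 636 (379 and 257) at adjusted p 0.01, and 1164 (615 and 549) without the 4 chromosomes, which left fewer genes. With the replicate block it was 413 (260 and 153), but same-numbered arrays did not deviate together (r = 0.05, -0.02 and -0.02), so the numbers are not a pairing. Without 1 array it ran from 945 to 1138 (512 to 606 higher, 414 to 532 lower), with fewer samples in each fit. Quantile normalization, centring, array weights, the dim filter, pseudocounts of 1 and 64, all probe sets, other probe set rules and chromosome medians gave 1510 to 2970. The deposited arrays already shared a common distribution, so quantile normalization and centring could move the count little. Of the 27 lists, 6 passed camera with the preset correlation, 0 with an estimated correlation and 16 with fry. With the block the ERK feedback list had adjusted p = 0.0625; G1/S genes had 0.0639 with the probe set of largest interquartile range, and G2/M genes 0.000577 without the 4 chromosomes. The rule named 131 genes besides Pik3ca, some of them not called in the main fit. Of these, 56 lost their call with the block, 19 with the mean of probe sets, 11 with chromosome medians taken out and 14 to 20 without 1 array. With the probe set of largest interquartile range, 10 lost their call without a change of sign. Another 4 reversed and lost their call as well, namely Fdft1 (-0.24), Polr1a (-0.29), Egr3 (0.72) and Cdc42ep5 (-0.20). The cause was not tested. The 3' to 5' differences of Gapdh and beta-actin stayed within 1 SD of their values. Signal over background was not measured, which limits what can be said of dim genes.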

Other observations

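The gastrointestinal list was written and tested only after the largest changes were seen, and the chromosome blocks were examined after the data were seen. In that list 11 of 50 measured genes rose and 1 fell, and the others were not past the threshold. Vil1, which encodes the microvillus protein villin, rose by 2.57, the gut keratin gene Krt20 by 2.44, the galectin gene Lgals2 by 2.02, Dmbt1 by 1.84 and the gastric protease gene Ctse by 1.76. The lipoprotein gene Apoa1 rose by 1.51 and the thyroxine carrier gene Ttr by 1.06. Of the rises, Vil1, Dmbt1, Apoa1, Ttr, Anxa13 and Myo1a stayed below the median brightness of all genes in both groups. Dmbt1 went from an intensity of 19.3 to 115, Apoa1 from 19.4 to 87.1 and Ttr from 39.5 to 99.8. Only 1 of 4 probe sets rose for Apoa1 and for Ttr. The probe sets of Dmbt1 and Myo1a did not pass when all probe sets were tested. Fabp2, an enterocyte fatty acid binding protein gene, fell by 1.38 on the log2 scale. The median over the 50 measured members was 0.08, so most of the list moved little.

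Neighbouring genes also moved together in 2 short stretches, beyond the largest window median of 0.41 in 100 permutations. A stretch of 39 tested genes on chromosome 16 (GRCm38.p6), from Mefv to Alg1, had a median change of 0.50, with 21 genes higher and 0 lower by limma. A stretch of 21 genes on chromosome 5, from Ubl3 to Stard13, had a median of -0.45, with 0 higher and 5 lower.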
